A study of Rattus norvegicus with 9 samples.

How the data were processed

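RNA was sequenced from kidney tissue in 9 samples that the labels place in 3 groups of 3: normal animals (WT), hypertensive animals (Model) and hypertensive animals given Qingda granule, a Chinese herbal preparation (QDG). The age stated for all groups was 6 weeks. Per the labels' protocols, total RNA was extracted with Trizol, its integrity was checked on a Bioanalyzer, ribosomal RNA was removed with a depletion kit, and libraries were built with an NEB Next Ultra RNA kit. Because ribosomal RNA was depleted and no poly(A) selection is described, unspliced and non-polyadenylated RNA can contribute to the values. The strain, the way hypertension arose, the dose of the granule and whether the 3 samples of a group came from separate animals are not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be technical.

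The authors deposited 1 value per feature and sample, and the unit is not written with the values. It was taken to be FPKM, reads or fragments scaled to the length of the feature in kilobases and to the library total, because the deposited values of each feature moved in steps that depended on the feature and the library in the way that whole reads divided by length and library size do. Whole reads were recovered on this basis for 17859 of the 17862 features (99.98%), within an absolute tolerance of 0.0001 read or a relative one of 2e-07, and 99.9% of the recovered lengths were whole bases within 0.05 base. The steps do not tell single reads from read pairs. The lengths used below are those recovered from the steps, with a median of 3711 bases. The same 17862 features stood in every sample in the same order and no value was 0, so features at 0 in some sample were not analysed here. The submitters' processing notes name limma. The aligner, the counter, the genome build and the annotation are not given in the sources used here.

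The labels give the brown rat as the organism, while 17553 features carry identifiers that begin with ENSMUSG, the prefix that Ensembl gives to mouse genes, and the other 309 carry a label that marks them as new features, followed by a running number, in place of an Ensembl identifier. What the submitters meant by this label is not given in the sources used here. A table of 47357 rat genes of the GRCr8 assembly was at hand, but it lists no Ensembl identifiers, so its 0 matches were fixed by the format and say nothing about the species. Whether mouse RNA was sequenced or rat reads were assigned to a mouse annotation cannot be settled from the identifiers, and in the latter case values would also vary with how well each gene's sequence matches between the species. The files do not pair identifiers with gene names, and no name was assigned. The 52 gene lists fixed before the data were examined, which are written in gene symbols, matched 0 identifiers. Their tests and the planned gene set tests with camera and fry were not run.

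Features with a mean of at least 1 FPKM over the 9 samples were tested (12187 features, 213 of them without an Ensembl identifier). Values were transformed as log2(FPKM + 1), and 1 limma model with an intensity trend was fitted to all 9 samples, which share one estimate of the spread. Model was compared with WT, QDG with Model, and QDG with WT. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and features with an adjusted p under 0.05 are called higher or lower. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of features with low values. The rule for naming genes, fixed before the data were examined, took features with an adjusted p under 0.05, a mean of at least 1 FPKM and all 3 values of one group above all 3 of the other, ordered by log2 change, and required a gene symbol. The symbol requirement excluded every feature, so it was dropped, and identifiers are given for 2 features that rose and 2 that fell in Model. For QDG against Model, the feature with the smallest p in each direction is given.

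The FPKM steps imply library totals of 26.2 M (WT 1) to 31.4 M (WT 3) reads or fragments, of which 24.0 M (WT 2) to 26.9 M (Model 1) lay in the listed features. At these depths 1 read over 1 kb of length corresponds to 0.0318 to 0.0382 FPKM. Counts of same-group libraries differed by far more than counting noise, with a chi-square per degree of freedom between 11.4 (QDG 1 and QDG 2) and 60.5 (WT 1 and WT 3), so no library's counts repeated those of another library of its group within counting noise. This does not exclude repeat preparations from 1 animal.

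The procedure was tested on simulated values for Model against WT over 12184 features, with 100 features changed by a log2 of 0.5 and 100 by a log2 of 1 before the pseudocount. It recovered 6% of the former and 78% of the latter, with median estimates of 0.39 and 0.81, and 3 of its 87 calls were false. A simulated comparison of QDG with WT without changes gave 0 calls. This was 1 simulated data set with independent features, no length trend and the same spread in all groups. The data had unequal spread between groups, so these counts do not give the rate of false calls in the data. The correlation between comparisons that share libraries was simulated with 100 draws of unchanged groups. After the data were seen, 100 further draws kept the observed mean of WT and gave Model and QDG 1 common mean, as a reference in which QDG does not differ from Model, and another 100 kept the mean of Model and gave QDG and WT 1 common mean, as a reference in which QDG does not differ from WT. All draws treat features as independent, so they leave out variation that many features share, such as a trend on length, and their ranges are too narrow to that extent. They also give the 3 groups 1 common spread per feature, whereas the median SD was 0.19 in WT, 0.15 in Model and 0.09 in QDG. Simulated values themselves, and not only their ranges, can therefore be off. In the references with a kept difference, observed means served as true means. Their sampling error thus counts as a difference, which can make the simulated differences too large.

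Alternatives fixed before the data were examined were quantile normalization, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, a fit to only the 2 groups compared, the replicate number as a block, added limits on fold change, and leaving out each sample in turn. Alternatives chosen after seeing the data were limma voom on the recovered reads, with libraries scaled by the median ratio or by total reads, removal of each library's trend on feature length with a lowess curve of span 0.4, and calling features without 1 Model or 1 WT library before QDG was set against that library. The count-based tests were planned only for the case that counts were deposited, and of the count-based methods only voom was run on the recovered reads. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.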

Results

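Gene expression in kidney tissue was measured by sequencing of ribosomal RNA-depleted RNA in 3 normal samples (WT), 3 samples from hypertensive animals (Model) and 3 from hypertensive animals treated with Qingda granule (QDG), all at 6 weeks of age. The design addresses which genes differ in the hypertensive kidney and which of them respond to the granule. Implied library totals lay between 26.2 M and 31.4 M reads or fragments. The median feature stood at 2.59 FPKM (Model 3) to 2.76 FPKM (WT 3), and 31.6% to 33.3% of the 17862 features were under 1 FPKM in a library. The 10 most abundant features held 34.2% ± 4.70 (SD, n = 3) of the summed FPKM in WT, 29.7% ± 1.43 in Model and 32.2% ± 2.76 in QDG. Features are given by identifier because the files do not pair identifiers with gene names.

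WT kidneys lay apart from both hypertensive groups. On the principal component that held 35.9% of the variance of log2(FPKM + 1), the WT libraries stood at −25.2, −25.8 and −15.0, the Model libraries at 16.7, 5.98 and 20.6, and the QDG libraries at 12.5, 6.46 and 3.78. The next component held 21.9% and did not separate WT from the other groups. Its values were −7.69 to −16.0 in QDG and −2.43 to 17.9 in Model. Across features, the mean Pearson correlation was 0.968 between WT and Model libraries, 0.972 between WT and QDG, and 0.982 between Model and QDG. Within groups it was 0.977 in WT, 0.983 in Model and 0.991 in QDG. Libraries of Model and QDG correlated with each other about as closely as Model libraries did among themselves, but less closely than QDG libraries did. All QDG libraries also lay below all Model libraries on the component that held 21.9% of the variance.

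**Figure D1:**
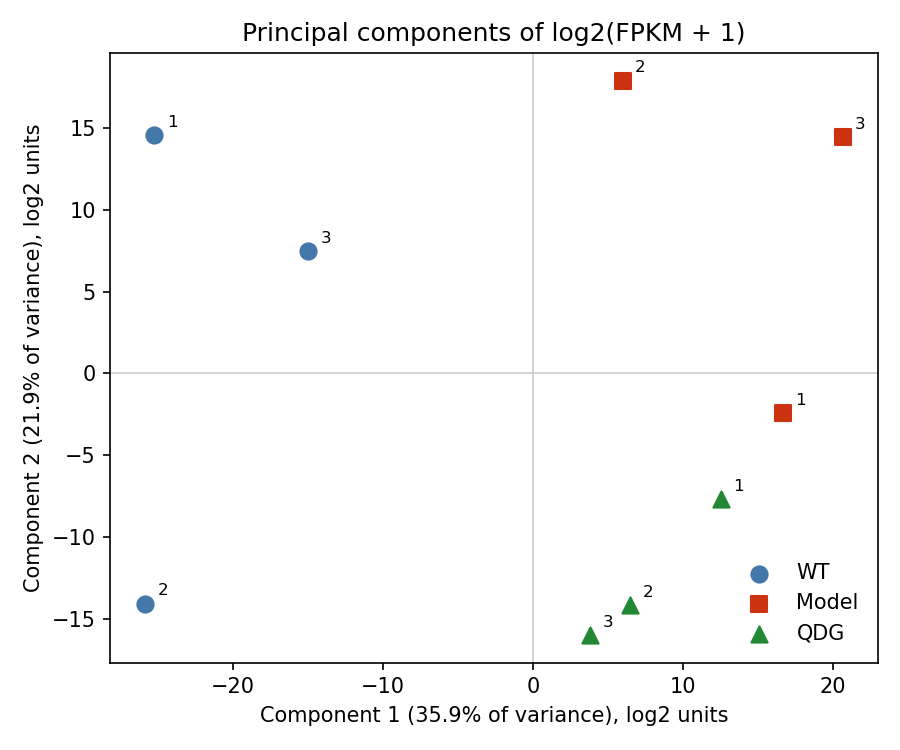
Each point is 1 library, placed by its scores on the leading components of log2(FPKM + 1) over 12187 features, in log2 units; colour and shape give the group and the digit the replicate. The 3 WT libraries lie between −25.8 and −15.0 on the horizontal axis and all Model and QDG libraries between 3.78 and 20.6.

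The comparison of Model with WT addresses what differs in the hypertensive kidney. The strain and any processing batches are not given in the sources used here. Hypertension therefore cannot be told apart from other differences between these groups. In Model, 732 features were higher and 231 lower than in WT (963 of 12187; limma, adjusted p under 0.05). The median log2 change was 0.64 among those higher and −0.58 among those lower, and 121 of the 963 changed by 2-fold or more (88 higher, 33 lower). ENSMUSG00000067144 rose most, from 5.50 ± 0.886 FPKM (SD, n = 3) in WT to 56.2 ± 10.7 in Model, a log2 change of 3.13 with an SE of 0.26 (limma adjusted p = 0.000752). ENSMUSG00000038567 rose from 3.68 ± 5.001 FPKM to 15.0 ± 4.18, a log2 change of 2.28 with an SE of 0.61 (limma adjusted p = 0.0479). WT 3 alone stood at 9.45 FPKM for this feature and the other WT libraries at 0.643 and 0.950, and its call held under 4 of 18 alternatives. The largest fall was in number 164 of the features that the files mark as new and give no Ensembl identifier, from 98.8 ± 15.0 FPKM in WT to 9.08 ± 5.70 in Model, with a log2 change of −3.44 and an SE of 0.35 (limma adjusted p = 0.00210). ENSMUSG00000027875 fell from 313 ± 39.2 FPKM to 41.3 ± 43.1, with a log2 change of −3.39 and an SE of 0.53 (limma adjusted p = 0.0112). Its Model libraries were uneven, at 12.9, 20.04 and 90.9 FPKM. The least covered library held 252 recovered reads for ENSMUSG00000067144, 60 for ENSMUSG00000038567, 126 for feature 164 and 1218 for ENSMUSG00000027875.

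**Figure D2:**
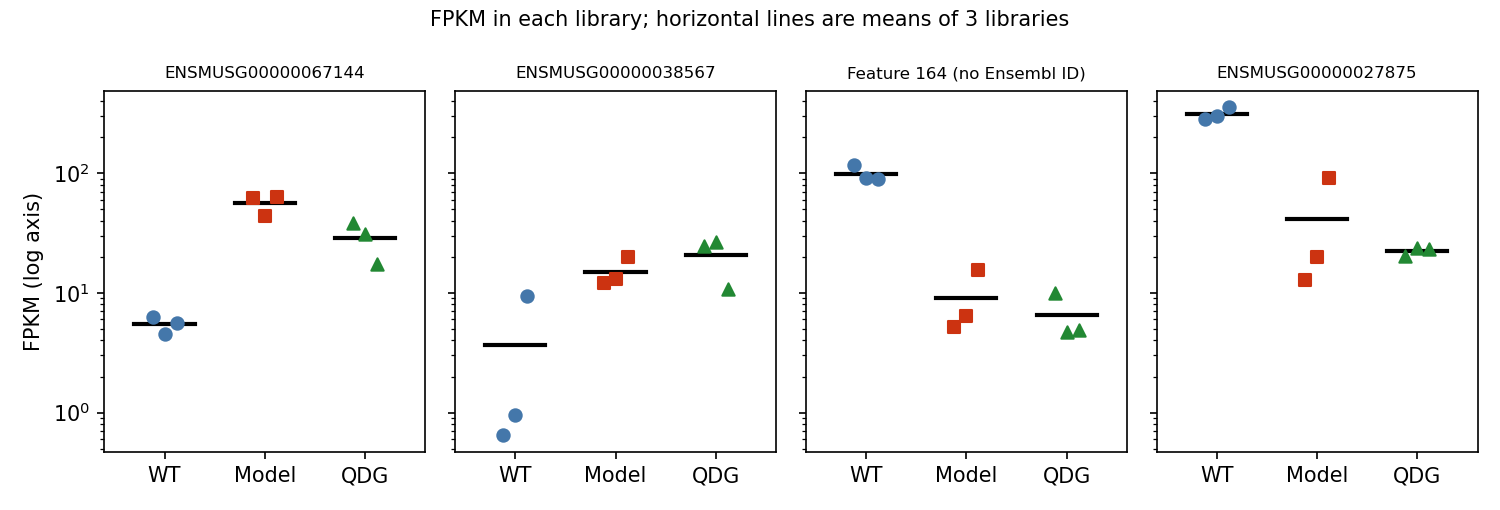
FPKM on a log axis in each of the 9 libraries for the 2 features that rose most and the 2 that fell most in Model against WT; points are libraries and horizontal lines are group means of 3 libraries. ENSMUSG00000067144 has a mean of 5.50 FPKM in WT, 56.2 in Model and 28.9 in QDG, while feature 164 has means of 98.8, 9.08 and 6.52 FPKM.

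Abundant features were called more often in Model than scarce ones, and mostly as higher. The log2(FPKM + 1) scale understates changes at low values, so the lower rate among scarce features can follow in part from the scale. The classes below were counted on the deposited FPKM. Of the 5521 features with a mean of 1 to 5 FPKM, 163 were higher and 125 lower. Of the 4276 at 5 to 20 FPKM, 274 were higher and 66 lower. At 20 to 100 FPKM, 215 of 1854 were higher and 21 lower, and at 100 FPKM and over, 80 of 536 were higher and 19 lower. Features without an Ensembl identifier were called at a rate of 9.39% (10 higher and 10 lower of 213), against 7.88% of the 11974 others, a difference that did not pass the test (Fisher's exact test, two-sided, p = 0.440, adjusted over 3 comparisons p = 0.660; features are not independent replicates).

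Short features were also more often higher in Model. Of the 1193 features under 1000 bases, 139 were higher and 27 lower, while of the 3252 over 6000 bases, 53 were higher and 85 lower. The median length was 2297 bases among the features higher in Model, 4709 among those lower and 3859 among all tested. Across features, Spearman's rho between length and the log2 change of Model against WT was −0.35. Within single libraries, rho between length and the deviation from the mean of the 9 libraries was −0.16, −0.25 and −0.48 in Model, −0.05, 0.37 and 0.12 in WT, and −0.07, 0.30 and 0.27 in QDG, for replicates 1, 2 and 3 in that order. Features are not independent replicates, and no p-value was attached to these correlations.

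**Figure D3:**
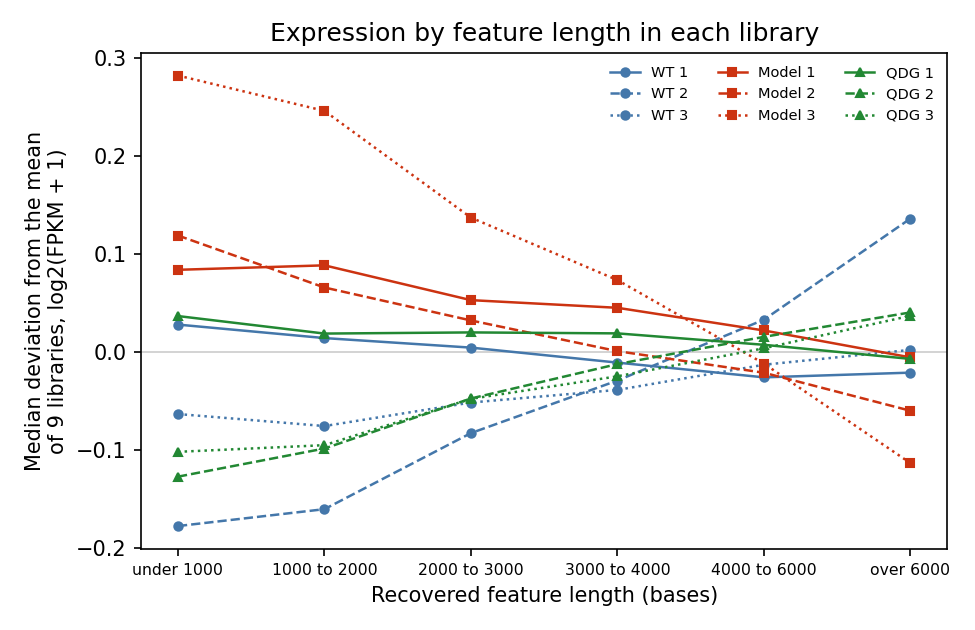
Median deviation of each library from the mean of the 9 libraries, in log2(FPKM + 1), for 6 classes of feature length in bases; each line is 1 library, with colour and marker for the group and line style for the replicate. For features under 1000 bases the Model libraries stand at 0.08, 0.12 and 0.28, above the WT libraries at 0.03, −0.18 and −0.06.

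The excess of higher features in Model varied with how the values were processed. Of the called features, 76.0% were higher in the deposited FPKM (732 and 231), 60.4% after quantile normalization (431 and 283), 62.6% after removal of the length trend (477 and 285), and 61.0% or 51.6% with voom on recovered reads scaled by the median ratio (674 and 431) or by total reads (456 and 427). The shared estimate of the spread included the QDG libraries, which varied less. The median residual SD was 0.16 with all 9 libraries and 0.18 with the WT and Model libraries alone, a fit that called 144 features. That fit also had fewer degrees of freedom (a median of 8.66 against 10.2), and no test separated spread from degrees of freedom. The number called was 413 without WT 1, 240 without WT 2, 1529 without WT 3, 294 without Model 1, 195 without Model 3, 626 without QDG 1, 399 without QDG 2 and 561 without QDG 3. All 3 values of one group lay above all 3 of the other for 28.2% of features (2114 higher and 1326 lower in Model), where chance gives 10%. The share was nearly as large for QDG against Model (26.7%) and for QDG against WT (27.7%).

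The comparison of QDG with Model addresses what the granule changed in the hypertensive kidney. No feature passed the threshold (0 of 12187; limma, lowest adjusted p = 0.0707), and voom on recovered reads also called 0 under both scalings. The shared estimate of the spread included the WT libraries, which varied most. A fit to only the Model and QDG libraries had a median residual SD of 0.13 against 0.16, with fewer degrees of freedom (7.43 against 10.2). It called 1 feature and had 2286 at an unadjusted p under 0.05. The 963 and 0 calls therefore do not compare the sizes of the 2 differences. In the fit to all 9 libraries, 1695 features had an unadjusted p under 0.05, 520 higher and 1175 lower in QDG, where chance gives 609. This balance varied with the processing. After quantile normalization 683 were higher and 755 lower. Voom gave 786 and 957 when scaled by the median ratio, and more higher than lower (888 and 718) when scaled by total reads. ENSMUSG00000056749 had the smallest p, with 4.75 ± 0.397 FPKM (SD, n = 3) in Model, 1.44 ± 0.216 in QDG and 2.31 ± 0.625 in WT. The log2 difference was −1.24 with an SE of 0.15 (limma adjusted p = 0.0707). Its values were low, with 74 to 316 recovered reads per library, and it fell below the alternative limit of a mean of 5 FPKM. This feature was also called higher in Model against WT (log2 change 0.81, limma adjusted p = 0.0162). In QDG against Model it passed in the fit without WT 3 and in the fit to only the Model and QDG libraries. The smallest p in the other direction belonged to ENSMUSG00000055805, with 9.18 ± 0.334 FPKM in Model, 16.6 ± 1.85 in QDG and 12.6 ± 1.502 in WT. Its log2 difference was 0.78 with an SE of 0.11 (limma adjusted p = 0.156). ENSMUSG00000067144 stood at 56.2 ± 10.7 FPKM in Model and 28.9 ± 10.7 in QDG (log2 difference −0.99, limma adjusted p = 0.282). Feature 164 stood at 9.08 ± 5.70 and 6.52 ± 2.96 FPKM, ENSMUSG00000027875 at 41.3 ± 43.1 and 22.4 ± 1.97, and ENSMUSG00000038567 at 15.0 ± 4.18 and 20.7 ± 8.58, and none of these differences passed (limma adjusted p = 0.674, 0.785 and 0.807). Before adjustment for the number of features, the 95% interval of a log2 difference had a median half-width of 0.29, and passing the adjusted threshold takes a larger difference than that.

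Feature length ran the opposite way in this comparison, with a Spearman's rho of 0.45 across features. The median log2 difference of QDG against Model was −0.22 for features under 1000 bases and 0.09 for those over 6000 bases. After removal of each library's length trend, 651 features were higher and 660 lower at an unadjusted p under 0.05, and 0 passed the adjusted threshold. Fits without WT 3, Model 1, Model 3 or QDG 2 called 1, 3, 1 and 1 features, and a fit to only the Model and QDG libraries called 1.

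The comparison of QDG with WT shows which differences from normal kidney were present under treatment. In QDG, 199 features were higher and 102 lower than in WT (301 of 12187; limma, adjusted p under 0.05), with median log2 changes of 0.76 and −0.74, and 76 changed by 2-fold or more. ENSMUSG00000067144 was higher in QDG than in WT by a log2 of 2.14 (limma adjusted p = 0.00649). Feature 164 and ENSMUSG00000027875 were lower, with log2 changes of −3.79 (limma adjusted p = 0.00141) and −3.75 (limma adjusted p = 0.009999). ENSMUSG00000038567 did not pass, with a log2 difference of 2.65 (limma adjusted p = 0.0507). At 100 FPKM and over, 8 features were higher and 15 lower, while at 20 to 100 FPKM 51 were higher and 14 lower. Of the features without an Ensembl identifier, 2 were higher and 5 lower (3.29%, against 2.46% of the others; Fisher's exact test, two-sided, adjusted p = 0.660). Length and log2 change were almost unrelated across features here, with a Spearman's rho of −0.04. The number called was 515 after quantile normalization, 519 after removal of the length trend and 486 with only the WT and QDG libraries. It was 73 without WT 1, 775 without WT 3, 515 without Model 2, 44 without QDG 1, 39 without QDG 2 and 65 without QDG 3.

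Part of the features called against WT were called in both hypertensive groups. Features called higher in both Model and QDG against WT numbered 152, and 61 were called lower in both, where independent lists give 11.95 and 1.93. No feature was called in opposite directions. A further 750 features were called in Model alone and 88 in QDG alone, and the difference between those groups was not significant for any of them. The 213 shared features were 22.1% of those called in Model. Simulated groups without any effect had almost no calls and an overlap of 0 to 1. Over the features called in Model in each simulation, which are other lists than the 963, the shared part was 0.00239% where QDG did not differ from WT (a mean of 768 features) and 66.9% where QDG did not differ from Model (a mean of 1590). Observed means, sampling error included, served as true means there, so the 66.9% may be too high. Across features, the log2 changes of Model and of QDG against WT correlated at r = 0.74, against a mean of 0.50 in simulations without effects, and their covariance was 0.078 against a simulated 0.016. A mean of 0.50 follows from giving all groups 1 common spread. In the data WT varied most and QDG least (median SDs of 0.19 and 0.09). Sharing the WT libraries alone could therefore give a higher correlation and covariance than simulated. No split of the 3 WT libraries leaves 2 to each comparison. When features were called in Model without 1 WT library and QDG was set against that library, QDG differed in the same direction as Model for 84.0% (without WT 1), 96.2% (without WT 2) and 70.0% (without WT 3) of them, against 58.6%, 68.3% and 58.7% of all tested features.

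Among features called in Model against WT, 0 were called the opposite way in QDG against Model (limma). There was 1 such feature in each of the fits without WT 3, Model 1 or Model 3. At an unadjusted p under 0.05, QDG differed from Model in the direction opposite to the change in Model for 309 of the 963 and in the same direction for 9 (32.1% and 0.935%). The 963 were chosen with the same Model libraries, which favours the opposite direction. Simulations in which QDG did not differ from Model gave mean shares of 8.40% and 1.53%, and simulations without any effect, over as many features with the smallest p, 20.6% and 0.449%. The former simulations took observed means, sampling error included, as true means, so their 8.40% may be too low. Where QDG did not differ from WT, the shares were 92.3% and 0.0231%. The QDG mean lay between the WT and Model means for 802 of the 963 (83.3%), beyond the Model mean for 147 and beyond the WT mean for 14. The simulated share between the means was 72.8% (69.7% to 75.9% over 100 draws) without any effect, 66.1% (63.3% to 68.5%) where QDG did not differ from Model and 71.0% (66.6% to 74.6%) where it did not differ from WT, all below the observed 83.3%. The draws gave the groups 1 common spread, which the data did not have, so this gap alone does not show an intermediate QDG. QDG lay on the WT side of Model for 84.7%. The simulated mean of this share was 86.3% (83.7% to 88.9%) without any effect, 66.5% (63.7% to 68.7%) where QDG did not differ from Model and 99.6% where it did not differ from WT. The median log2 change over the 963, signed by the direction in Model, was 0.63 in Model and 0.42 in QDG against WT. Choosing features by their change in Model raises the former, and simulated values were 0.52 and 0.47 where QDG did not differ from Model, over a mean of 1590 called features, 0.54 and 0.07 where it did not differ from WT, over a mean of 768, and 0.31 and 0.15 without any effect. The covariance across features between the log2 changes of Model against WT and of QDG against Model was −0.037, where sharing the Model libraries alone, with 1 common spread for all groups, gave −0.016 (correlations of −0.46 and −0.50).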

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

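Voom on recovered reads and removal of the length trend were chosen after seeing the data; the other alternatives in this part were not. Model against WT called 963 features, 144 with only the 2 groups fitted, 121 with an added 2-fold limit and 153 with an unadjusted p and a 2-fold limit. Leaving out 1 library gave 195 (without Model 3) to 1529 (without WT 3). QDG against Model called 0, 1 with only the 2 groups fitted, 20 with an unadjusted p and a 2-fold limit, and 0 to 3 (without Model 1) with 1 library left out. QDG against WT called 301, 515 after quantile normalization, 486 with only the 2 groups fitted, 76 with an added 2-fold limit, 134 with an unadjusted p and a 2-fold limit, 519 after removal of the length trend, and 39 (without QDG 2) to 775 (without WT 3) with 1 library left out. Features called in Model and called the opposite way in QDG against Model numbered 0, 4 with an unadjusted p and a 2-fold limit, and 0 to 1 (without WT 3, Model 1 or Model 3) with 1 library left out. A fold limit selects fewer features by construction. The median residual SD (log2) was 0.162 with all groups, 0.179 with WT and Model alone, 0.133 with Model and QDG alone and 0.157 with WT and QDG alone. The median degrees of freedom of these fits were 10.2, 8.66, 7.43 and 8.44 in the same order. Spread and degrees of freedom changed at once. Apart from the fold limit, the cause of the changes in the counts was not tested. The remaining alternatives stayed within 1.5 times these counts, except the replicate block. With the replicate number as a replicate block, 533, 0 and 154 features were called in the order above. Same-numbered libraries did not deviate together (correlations of −0.33 to 0.14 between deviations from the group means), and not every library correlated best with its own number. These values gave no sign that the numbers pair the samples, but with 3 libraries per group they cannot exclude it.

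Of the 963 features called in Model against WT, 612 were also called after quantile normalization and 597 after removal of the length trend, in the same direction. ENSMUSG00000067144, ENSMUSG00000027875 and feature 164 kept their direction and side of the threshold under 18 of 18 alternatives that refitted the model. ENSMUSG00000038567 kept its direction, with log2 changes of 1.80 (without WT 1) to 3.13 (without WT 3), but passed under only 4. Count-based normalization and tests, including DESeq2, were planned only for deposited counts and were not run; of such methods only voom was applied to the recovered reads. In addition, the gene set alternatives were not run because no gene list could be matched. Depth limits features with few reads: 1 read over 1 kb was worth 0.0318 to 0.0382 FPKM.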

Other observations

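The tests of other splits, the scaling test of the higher share in Model and the depth test of the QDG spread were chosen only after the results were seen, and removal of the length trend and the left-out Model libraries are alternatives added after seeing the data, with bounds set before their results were seen.

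For each comparison, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 963 features for Model against WT and the highest of the other splits 1, so 1 of 10 splits, the real one, called as many. For QDG against WT the real split called 301 and the highest other 0, again 1 of 10. For QDG against Model the real split called 0, which all 10 splits reached, and the highest other called 1. At an unadjusted p under 0.05 the real split of QDG against Model gave 1695 features and the highest other 670.

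More features were higher than lower in Model against WT. Library-wide scaling may account for part of this excess, since the share higher went from 76.0% to 60.4% with quantile-normalized values, between the bounds of 55% for and 65% against it. The share was 61.0% and 51.6% with voom scaled by the median ratio and by total reads. The bounds were set for quantile-normalized values only, and voom also changed the model, so the voom shares do not decide the question. A length trend between libraries is a further candidate: its removal left 762 features called and 62.6% of them higher. The count of 762 met the bound set against this explanation beforehand, but that bound concerned the number of calls and not their direction, so it leaves the excess open. A change of composition in the hypertensive kidney also stays open and was not tested.

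For features called in Model against WT, QDG means tended to lie between WT and Model. The share between the means, 83.3%, was above the range simulated without any effect (69.7% to 75.9%). It was also above those with QDG equal to Model (63.3% to 68.5%) and with QDG equal to WT (66.6% to 74.6%). The opposite-direction share at an unadjusted p, 32.1%, was outside the ranges of the same simulations (16.2% to 24.3%, 7.02% to 10.1% and 90.3% to 94.7%). The 84.7% on the WT side of Model lay within the 83.7% to 88.9% without any effect. Draws of independent features make all these ranges too narrow. The draws also gave the groups 1 common spread per feature, while QDG varied least and WT most. The gaps between observed and simulated shares therefore cannot be assigned to an intermediate QDG. When features were called without 1 Model library and QDG was set against that library, the shares on the WT side were 76.9% (without Model 1), 49.3% (without Model 2) and 65.1% (without Model 3), against 64.2%, 54.5% and 61.5% of all tested features, so the sharing of Model libraries stays open. The shares were 67.0%, 43.3% and 54.5% with the length trend removed, against baselines of 61.6%, 49.97% and 56.7%, and 68.6%, 39.5% and 52.7% with quantile normalization, against 61.8%, 53.4% and 58.4%; both met the bounds set beforehand, 55% or less for at least 2 of the 3 libraries for a length trend and a lowest share of 55% or less for scaling, the latter already met by the deposited values at 49.3%, and under both settings only the fit without Model 1 stood above its baseline. A length trend and library-wide scaling may therefore each account for part of the pattern, these values favour neither, and a partial response to the granule remains an open hypothesis.

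QDG libraries varied less around their group mean than the others. The median SD over features was 0.09 in QDG, 0.15 in Model and 0.19 in WT, in log2(FPKM + 1), a ratio of 0.56 between QDG and the mean of the others. Counting noise at low values, and greater depth as far as it acts through counting noise, are argued against by a ratio of 0.52 among the 2390 features of at least 20 FPKM. By implied totals, WT 3 (31.4 M) and Model 2 (30.0 M) were deeper than every QDG library (28.3 M to 29.3 M). These libraries also deviated more from their group means, with SDs of 0.22 and 0.21 against 0.12 to 0.14 in QDG. WT 1 (26.2 M), WT 2 (26.3 M) and Model 3 (26.8 M) were shallower. By reads recovered in the listed features, Model 1 (26.93 M) and Model 3 (26.13 M) lay above every QDG library (25.09 M to 26.08 M). Their SDs were 0.17 and 0.20. WT 1 and WT 2 (24.0 M) lay below every QDG library. Joint handling of the QDG samples and a narrower range among treated animals both remain open and untested.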
